A study of Arabidopsis thaliana with 12 samples.

How the data were processed

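RNA was measured by sequencing in 12 libraries of 7-day-old Arabidopsis thaliana seedlings grown at 21 °C in short days. The labels put 3 libraries in each of 4 genotypes: the wild type Col, h3.3kd (a knockdown of the histone variant H3.3, labelled as line h3.3kd-1), h2a.z (a mutant of the histone variant H2A.Z) and h3.3kd;h2a.z, which combines both and is called the double mutant here. Per the labels' protocols, total RNA was extracted with a Takara MiniBEST plant kit and libraries were built with an NEBNext Ultra kit. How poly(A) RNA was selected, whether strand was kept, and which mutant alleles were combined are not given in the sources used here. Nothing says that the libraries of a group came from separate growths, so p-values measure only the spread between these libraries.

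The authors deposited 1 table of TPM values (abundance scaled to a fixed library total and corrected for gene length), with 1 column per library and 23893 genes. The submitters' processing notes name fastp 0.20.1, HISAT2 2.1.10, HTSeq 0.11.2, DESeq2 1.26.0 and the genome build TAIR10, without role or order. How the deposited TPM were computed and how the listed genes were chosen is not given in the sources used here. Each column sums to 1000000, so a rise of abundant transcripts lowers the TPM of all others. The table lists 23739 nuclear, 86 plastid and 68 mitochondrial gene identifiers, and 99 genes are at 0 in every library.

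Gene symbols came from the RefSeq gene table of TAIR10.1, in which 23739 identifiers matched and the 154 organelle identifiers did not, and from the gene lists fixed beforehand. That build differs by name from the build of the notes and the deposited table holds no coordinates, so none are printed. The reference was used for symbols, annotated products, exonic lengths and the order of genes. Genes with near-identical copies, such as the light-harvesting, Rubisco small subunit, histone and clustered resistance genes, can share reads, and their separate values are uncertain. The same holds for overlapping and antisense genes.

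TPM keeps no total count, but low values fall on steps of whole reads. In 2687 genes with at most 3 expected reads a library, 97.61% of the values above 0 were whole multiples of the gene's smallest step within a tolerance of 0.01 steps. These steps gave the relative depth of the libraries, and with exonic lengths an approximate number of reads. The estimate was between 19800000 and 30500000 reads in the other libraries and about 5230000 in h2a.z replicate 1, in which 1 read weighs 3.85 times as much as in Col replicate 1.

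Tests were run with limma 3.58.1 in R 4.3.3 on log2(TPM + 1) over 18851 genes with a mean TPM of at least 1. A linear model with 4 genotype groups was fitted to all 12 libraries, with 8 residual degrees of freedom and a variance moderated along a mean-variance trend. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 are described as called. There were 6 contrasts: each mutant against Col, the double mutant against each single mutant, and the interaction, which asks whether the double mutant departs from the sum of both single effects on the log2 scale. Fold changes are on the log2(TPM + 1) scale and understate changes of low genes.

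Of 24 gene lists fixed beforehand with 331 genes, 22 were tested with camera in limma at a preset correlation of 0.01, over 132 list tests adjusted together. The H3.3 and H2A.Z genes were reported as targeted genes. The other lists cover H3.1 genes, other H2A genes, H2A.Z and H3.3 machinery, thermomorphogenesis, auxin response, heat shock, flowering time, circadian clock, salicylic acid and immunity, jasmonate, abscisic acid with cold and drought, flavonoid and anthocyanin, glucosinolate, photosynthesis, cell cycle, phosphate starvation, iron deficiency, senescence, seed maturation, floral and meristem regulators, root markers and reference genes. The 4 list members HSP22, PDF1.2B, MYC2 and SAG12 were not analysed here. Calls within a list are counted over all genes tested and again adjusted over the list alone. Groups of genes sharing an annotated product, 177 with at least 10 tested genes, were tested the same way after the data were seen.

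The text names genes by a rule set before the data were examined. It takes HTR4, HTR5, HTR8, HTA8, HTA9 and HTA11 in each comparison, and PIF4, YUC8, IAA19, IAA29, HSP70 and FLC against Col. It takes the 5 largest rises and 5 largest falls of each comparison with Col among called genes with a mean TPM of at least 5 in 1 of the groups and no overlap of the 3 and 3 libraries. For the interaction it takes the 3 most positive and the 3 most negative genes, and for each list described up to 4 called members with the largest changes. Members of the 46 nearly silent genes and of annotated groups outside this rule were chosen after their values were seen.

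The overlap of the single mutants was set against 100 simulated data sets of unchanged groups with shared Col libraries, and the double mutant against 100 simulations with additive effects, both with the observed spread. In data simulated for h2a.z against Col over 18851 genes, 60% of 50 genes with a log2 change of 0.5 were recovered, 98% at 1 and 100% at 2 and at 4, with 11 false calls among 190. A list of 20 genes shifted by 0.5 gave a camera p of 9.22e-46 in that simulation, and 1 of 100 random lists fell below 0.05.

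Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean TPM of at least 5, TPM rescaled by median ratios, a robust or untrended variance prior, array weights, a 2-fold minimum, the replicate number as a block, only the 6 libraries compared, each library left out in turn, and for lists an estimated correlation or fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.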

Results

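The transcriptomes of 7-day-old seedlings were measured in 4 genotypes with 3 libraries each: the wild type Col, a knockdown of H3.3 (h3.3kd), a mutant of H2A.Z (h2a.z) and their combination (h3.3kd;h2a.z). H3.3 is the replacement variant of histone H3 and H2A.Z is a variant of histone H2A; both are placed in chromatin outside replication. The series is about the roles of both variants in growth responses to warmth, and these libraries come from plants kept at 21 °C. The comparisons ask what each loss changes and whether the knockdown of H3.3 alters the effect of losing H2A.Z. Libraries of a genotype correlated across genes at 0.987 to 0.996 (Pearson r of log2 values) and libraries of different genotypes at 0.939 to 0.977; genes are not independent replicates. The estimated depth was about 5230000 reads in h2a.z replicate 1 and between 19800000 and 30500000 in the other libraries.

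The targeted transcripts other than HTR5 were low in the libraries labelled with them. HTR4 (AT4G40030), an H3.3 gene, had 386 ± 3.41 TPM (SD, n = 3) in Col, 36.2 ± 1.73 in h3.3kd and 35.4 ± 5.24 in the double mutant. HTR8 (AT5G10980), another H3.3 gene, had 187 ± 4.35 TPM in Col, 12.8 ± 0.846 in h3.3kd and 10.2 ± 2.63 in the double mutant. HTR5 (AT4G40040), the remaining H3.3 gene of the list, had 207 ± 2 TPM in h3.3kd against 250 ± 12 in Col, a log2 fold change of -0.27 (SE 0.06) that lost its call with rescaled TPM (adjusted p = 0.179). HTA8 (AT2G38810) had 9.2 ± 0.369 TPM in Col and 0.0746 ± 0.129 in h2a.z, and HTA11 (AT3G54560) had 24.4 ± 1.25 and 2.86 ± 0.425. HTA9 (AT1G52740), the most abundant H2A.Z transcript, fell from 161 ± 8.5 TPM in Col to 32.8 ± 4.06 in h2a.z, and stood at 60.5 ± 7 in the double mutant. The double mutant thus had 1.82 times the HTA9 level of h2a.z (log2 0.87, SE 0.09, adjusted p = 1.63e-06, limma), and HTA9 was called for the interaction (log2 1.22, SE 0.12). Against Col the double mutant had log2 fold changes of -3.42 (SE 0.08) for HTR4, -4.1 (SE 0.12) for HTR8 and -0.43 (SE 0.06) for HTR5, all called. They were -3.3 (SE 0.13) for HTA8, -1.4 (SE 0.09) for HTA9 and -3.24 (SE 0.12) for HTA11, also called. In h2a.z, HTR4, HTR5 and HTR8 differed from Col by -0.14, -0.10 and -0.09 and were not called; HTR4 was called there without double mutant replicate 2 (-0.14, adjusted p = 0.0413). HTA8 and HTA11 differed from Col by -0.11 each in h3.3kd and were not called; HTA9 was at -0.35 there and lost its call with rescaled TPM (adjusted p = 0.0926).

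**Figure D1:**
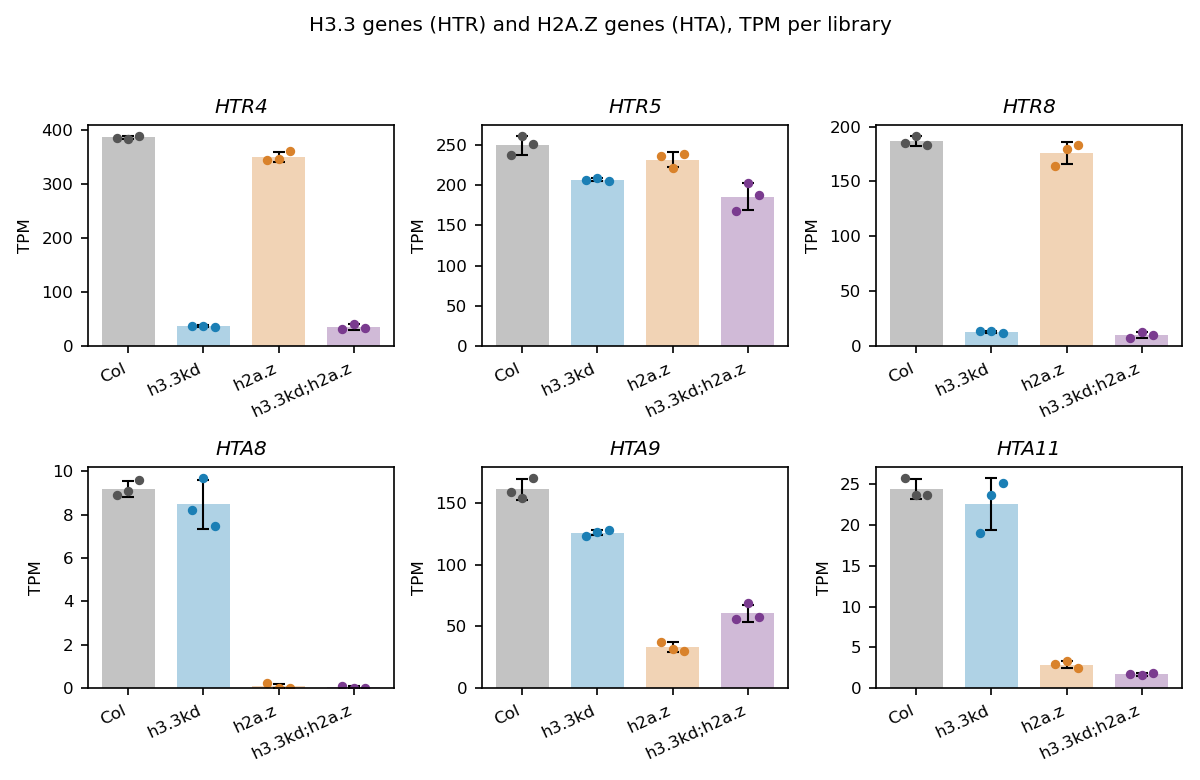
TPM (vertical axes, linear) of 3 H3.3 genes and 3 H2A.Z genes in the 4 genotypes; points are single libraries, bars are means of 3 libraries and error bars are SD. HTR4 and HTR8 are low in both genotypes with the H3.3 knockdown, HTR5 is not, and HTA9 is higher in the double mutant (60.5 TPM) than in h2a.z (32.8 TPM).

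In h3.3kd, the lists of H3.1 genes, other H2A genes, photosynthesis and glucosinolate were called as higher than other genes, and those of iron deficiency, of abscisic acid, cold and drought and of flavonoid and anthocyanin as lower, by camera with its preset correlation. None of these was called with an estimated correlation (adjusted p = 0.7254 for each). HIS1-3 (AT2G18050), a linker histone, rose from 19.3 ± 1.98 to 189 ± 25.9 TPM (SD, n = 3), 9.33-fold on the log2(TPM + 1) scale, and AT3G53730, annotated as a histone, rose from 73.6 ± 1.85 to 562 ± 10.6 TPM. PAP1 (AT1G56650), which activates anthocyanin genes, fell from 91.8 ± 3.38 to 9.3 ± 0.898 TPM. HSP70 (AT3G12580), a heat-inducible chaperone gene, fell from 173 ± 14.8 to 42.8 ± 9.29 TPM.

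Of 5 H3.1 genes, which encode the replication-coupled histone H3, 3 rose and none fell in h3.3kd, led by HTR3 (log2 0.83, SE 0.12), HTR2 (0.65, SE 0.09) and HTR1 (0.45, SE 0.07). Adjusted over the list alone the count was again 3, and the list was higher than other genes (camera adjusted p = 0.001282; adjusted p = 0.7254 with an estimated correlation). Among 9 other H2A genes 5 rose, or 6 adjusted over the list alone, and HTA7 rose by 1.01 (SE 0.09; list adjusted p = 0.0001119; adjusted p = 0.7254 with an estimated correlation). Of 20 photosynthesis genes 14 rose and none fell, or 17 adjusted over the list alone. LHCB1.2, a light-harvesting protein gene, rose by 0.98 (SE 0.08) and RBCS2B, a Rubisco small subunit gene, by 0.88 (SE 0.09); the list had an adjusted p of 1.363e-11 (adjusted p = 0.7254 with an estimated correlation). Of 18 glucosinolate genes 12 rose and 3 fell, over all genes and adjusted over the list alone. MAM3, a chain-elongation enzyme gene, rose by 2.17 (SE 0.18) and CYP79F2 by 1.43 (SE 0.15), while MYB29, a regulator of the aliphatic branch, fell by 2.02 (SE 0.14); the list had an adjusted p of 4.081e-05 (adjusted p = 0.7254 with an estimated correlation). Of 11 phosphate starvation genes 5 rose and 3 fell, also adjusted over the list alone, or 5 and 1 with rescaled TPM, with RNS1 at 1.55 (SE 0.16) and PHT1;4 at -0.85 (SE 0.11). That list was called at an adjusted p of 0.04031 (adjusted p = 0.7254 with an estimated correlation), and lost its call with rescaled TPM (adjusted p = 0.07) and without Col replicate 1 (adjusted p = 0.05).

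Of 13 iron deficiency genes 11 fell and none rose in h3.3kd, over all genes and adjusted over the list alone. IMA2 and IMA1, which encode iron-signalling peptides, fell by 1.54 (SE 0.14) and 1.12 (SE 0.20), the regulator gene PYE by 1.22 (SE 0.14) and NAS4 by 1.17 (SE 0.06); the list had an adjusted p of 0.0001119 (adjusted p = 0.7254 with an estimated correlation). Of 18 genes of abscisic acid, cold and drought 11 fell and none rose; adjusted over the list alone 11 fell and 1 rose. KIN1 fell by 1.46 (SE 0.11), HAI1, a phosphatase gene, by 1.28 (SE 0.19) and RD22 by 1.0 (SE 0.07), with an adjusted p of 0.004823 for the list (adjusted p = 0.7254 with an estimated correlation). Of 14 flavonoid and anthocyanin genes 9 fell and 1 rose, also adjusted over the list alone, with PAP1 at -3.17 (SE 0.10), PAP2, identifier AT1G66390, at -1.89 (SE 0.13) and DFR at -0.96 (SE 0.16). That list had an adjusted p of 0.01766 (adjusted p = 0.7254 with an estimated correlation). Of 18 heat shock genes 9 fell and none rose, also adjusted over the list alone, and 6 fell with rescaled TPM. HSP70 fell by 2.01 (SE 0.15), HSFA2, a heat stress transcription factor gene, by 1.57 (SE 0.17) and HSP101 by 0.91 (SE 0.09); the list as a whole was not called (adjusted p = 0.06316). Of 16 thermomorphogenesis genes 4 fell and none rose, also adjusted over the list alone: PIF7 (-0.46, SE 0.08), TAA1 (-0.36, SE 0.06), PIF5 (-0.34, SE 0.06) and EXPA8. The list as a whole was not called (camera adjusted p = 0.6768), and of all 18851 genes tested 5042 were called lower. EXPA8 lost its call with rescaled TPM (-0.31, adjusted p = 0.0837) and without any single Col or h3.3kd library (adjusted p from 0.0546 to 0.0891). PIF4, a transcription factor gene that promotes elongation in warmth, was at 0.07 (SE 0.08), YUC8 at -0.27 (SE 0.12) and IAA19 at 0.08 (SE 0.27), none called. FLC, a repressor of flowering, fell by 1.23 (SE 0.13). IAA29 was not tested: its mean TPM was 0.807 in Col, 0.442 in h3.3kd, 0.73 in h2a.z and 0.438 in the double mutant.

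Beyond HIS1-3 and AT3G53730, the largest rises by the rule were AT1G14250, a nucleoside phosphatase (log2 2.59, SE 0.14), AT5G03090 (2.53, SE 0.15) and AT2G05915 (2.5, SE 0.16). The largest falls were AT3G44970, a cytochrome P450 (-4.07, SE 0.11), AT1G75945 (-3.97, SE 0.12), HTR8 (-3.77, SE 0.12), AZI1, a gene of systemic immunity (-3.63, SE 0.12) and HTR4 (-3.38, SE 0.08). In total 6762 of 18851 genes were called, 1720 higher and 5042 lower, and 503 of them changed at least 2-fold, 123 higher and 380 lower. The median log2 fold change of all genes was -0.107, and rescaling TPM by median ratios moved it to about 0: 25.4% of the calls were higher as deposited and 50.9% (3241 higher, 3124 lower) with rescaled TPM.

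In h2a.z, the heat shock and jasmonate lists were called as higher than other genes and the photosynthesis and glucosinolate lists as lower, by camera with its preset correlation. None of these was called with an estimated correlation (adjusted p = 0.7443 for photosynthesis and 0.7254 for the others). HSP70 rose from 173 ± 14.8 to 563 ± 42.3 TPM (SD, n = 3), 3.24-fold. PIF4 (AT2G43010) rose from 14.6 ± 0.955 to 25.2 ± 1.55 TPM, 1.68-fold. CORI3, a jasmonate-responsive gene, rose from 4.35 ± 0.302 to 46.9 ± 1.58 TPM, and CYP83A1, an enzyme gene of aliphatic glucosinolates, fell from 60.3 ± 4.31 to 11.1 ± 1.82 TPM.

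Of 18 heat shock genes 12 rose and 2 fell in h2a.z, over all genes and adjusted over the list alone, with small heat shock protein genes in the lead: HSP17.6II at 2.55 (SE 0.18), HSP17.8 at 1.99 (SE 0.19) and HSP17.6C at 1.73 (SE 0.25). The list was higher than other genes (adjusted p = 0.003385; adjusted p = 0.7254 with an estimated correlation). Of 10 jasmonate genes 5 rose and none fell, also adjusted over the list alone, with CORI3 at 3.16 (SE 0.09), LOX2 at 1.39 (SE 0.14) and VSP2 at 1.3 (SE 0.20); the list had an adjusted p of 0.01865 (adjusted p = 0.7254 with an estimated correlation). Of 16 thermomorphogenesis genes 6 rose and 2 fell, also adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.5748). XTR7, a cell wall enzyme gene, rose by 1.46 (SE 0.15), PIL1 by 0.81 (SE 0.15) and PIF4 by 0.75 (SE 0.08). YUC8 was at 0.18 (SE 0.12) and IAA19 at -0.18 (SE 0.27), neither called. Of 18 glucosinolate genes 8 fell and 3 rose, also adjusted over the list alone. MAM1 fell by 3.01 (SE 0.12), CYP79F1 by 2.48 (SE 0.13), CYP83A1 by 2.35 (SE 0.11) and CYP79F2 by 2.01 (SE 0.15), all of the aliphatic branch. The list had a camera adjusted p of 0.006416 (adjusted p = 0.7254 with an estimated correlation). Its mean log2 fold change was -0.65 and its median -0.13, so the mean rests on few genes. MAM1 and CYP79F2 are also among the genes more than 8-fold below Col in h2a.z described below. For those genes chromosome segments from another strain stay open as an explanation. Of 20 photosynthesis genes 13 fell and none rose, also adjusted over the list alone, with LHCB4.2 at -1.08 (SE 0.07) and LHCB1.2 at -0.74 (SE 0.08); the adjusted p was 6.715e-05 (adjusted p = 0.7443 with an estimated correlation). Of 7 flowering time genes 5 fell and 1 rose, also adjusted over the list alone. MAF4 fell by 1.12 (SE 0.16), MAF2 by 1.01 (SE 0.12), MAF3 by 0.65 (SE 0.16) and FLC by 0.58 (SE 0.13), all repressors of flowering; the list was not called (adjusted p = 0.05512).

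The largest rises in h2a.z by the rule were AT3G25719 (log2 4.90, SE 0.25), AT4G24420, annotated as RNA-binding (4.69, SE 0.13), AT3G28320, AT5G66970 and MES18, a methyl esterase (4.2, SE 0.16). AT3G28320 and AT5G66970 were listed at 0 in all Col libraries and averaged 23.2 ± 3.25 and 20.3 ± 2.82 TPM in h2a.z. The largest falls were AT4G16880, a leucine-rich repeat gene with 65.5 ± 3.29 TPM in Col and listed at 0 in all h2a.z libraries, JAL33, a lectin (-5.85, SE 0.11), CNGC12, an ion channel (-5.41, SE 0.10), AT3G28270 (-4.82, SE 0.12) and AT1G13609, a defensin-like gene (-4.70, SE 0.22). In total 8900 genes were called, 5449 higher and 3451 lower, and 965 of them at least 2-fold, 570 higher and 395 lower. The share of higher calls was 61.2% as deposited and 49.1% (4583 higher, 4760 lower) with rescaled TPM.

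A count made after the data were seen found 46 nuclear genes with at least 5 TPM in Col and a mean more than 8-fold lower in h2a.z. They include HTA8 and HTA11, which are H2A.Z genes and thus targeted in this line. In the double mutant 23 of the 46, HTA8 and HTA11 included, were also more than 8-fold below Col, while 16 were at 50% of the Col mean or more. Among the latter were RPP5, a disease resistance gene with 30.1 TPM in Col, 0.361 in h2a.z and 24.5 in the double mutant, its neighbour RPP4 (24.6, 1.4 and 15.2 TPM) and AT4G19510 (16, 0.0797 and 15.1 TPM). CNGC12, JAL33 and MAM1 were low in both: CNGC12 had 58.5 TPM in Col, 0.399 in h2a.z and 0.107 in the double mutant.

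**Figure D2:**
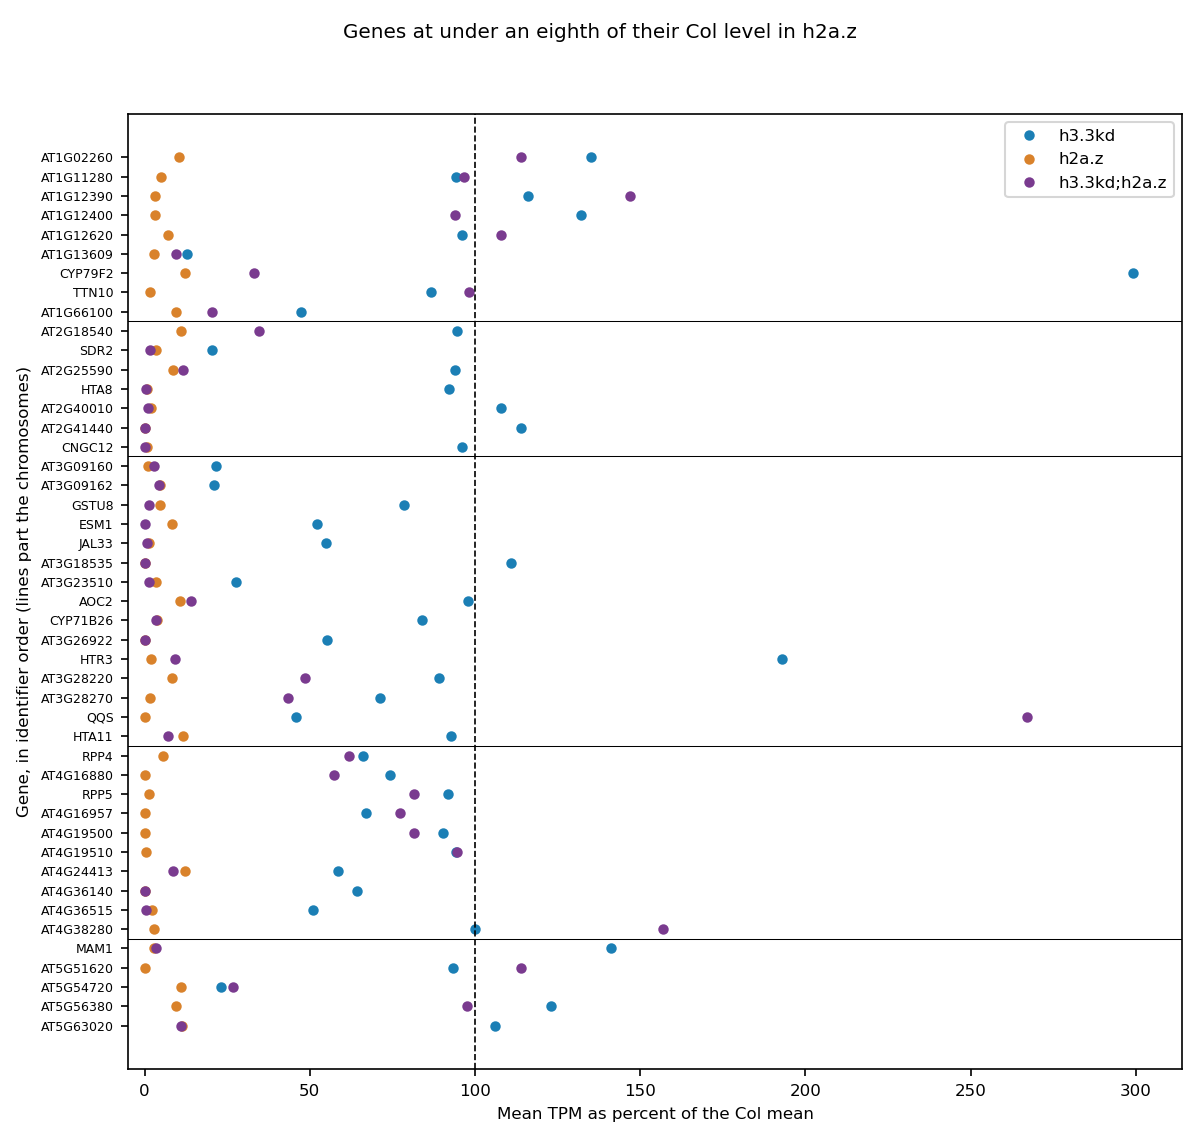
Mean TPM of h3.3kd, h2a.z and the double mutant as percent of the Col mean (horizontal axis, linear; means of 3 libraries) for the 46 genes more than 8-fold below Col in h2a.z, in the order of their identifiers (vertical axis). The double mutant lies near the h2a.z points for 23 of the genes and at 50% of Col or more for 16, RPP5 among them.

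In the double mutant, the lists of glucosinolate, of iron deficiency and of abscisic acid, cold and drought genes were called as lower against Col than other genes, by camera with its preset correlation. None of these was called with an estimated correlation (adjusted p = 0.7254 for each). CYP83A1 fell from 60.3 ± 4.31 to 1.06 ± 0.223 TPM (SD, n = 3) and MYB29 from 16.1 ± 1.65 to 0.837 ± 0.292 TPM. FLC (AT5G10140) fell from 5.37 ± 0.342 to 0.551 ± 0.0914 TPM, with 1.72 ± 0.372 in h3.3kd and 3.26 ± 0.406 in h2a.z. PIF4 had 15.1 ± 0.686 TPM, a log2 fold change of 0.04 (SE 0.08) that was not called, and HSP70 had 134 ± 29.4 TPM.

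Of 18 glucosinolate genes 12 fell and 2 rose in the double mutant, or 13 and 2 adjusted over the list alone, with CYP83A1 at -4.90 (SE 0.11), MYB29 at -3.23 (SE 0.14), MAM1 at -2.94 (SE 0.12) and CYP79F1 at -2.50 (SE 0.13). The list had an adjusted p of 0.0006114 (adjusted p = 0.7254 with an estimated correlation). Of 18 genes of abscisic acid, cold and drought 13 fell and 2 rose, or 14 and 2 adjusted over the list alone. KIN1 fell by 2.04 (SE 0.11), COR6.6 by 1.73 (SE 0.11), RAB18 by 1.70 (SE 0.20) and HAI1 by 1.3 (SE 0.19), with an adjusted p of 0.001282 for the list (adjusted p = 0.7254 with an estimated correlation). Of 13 iron deficiency genes 10 fell and none rose, or 11 adjusted over the list alone, with IMA2 at -1.71 (SE 0.14) and the ubiquitin ligase gene BTS at -1.53 (SE 0.09); the adjusted p was 0.002759 (adjusted p = 0.7254 with an estimated correlation). Of 7 flowering time genes 5 fell and 2 rose, also adjusted over the list alone, with FLC at -2.04 (SE 0.13), MAF4 at -1.27 (SE 0.16) and MAF2 at -1.09 (SE 0.12); the list was not called (adjusted p = 0.1917). Of 18 heat shock genes 5 rose and 6 fell, also adjusted over the list alone, and 7 rose and 4 fell with rescaled TPM; the list was not called (adjusted p = 0.3635). HSP18.2 rose by 1.54 (SE 0.15) and HSP90.1 by 1.52 (SE 0.10). HSP70 was at -0.39 (SE 0.15, adjusted p = 0.039), a call lost with rescaled TPM (adjusted p = 0.0992) and without Col replicate 1, 2 or 3 (adjusted p = 0.138, 0.0516 and 0.0628) or double mutant replicate 1 or 3 (0.142 and 0.151). YUC8 was at -0.26 (SE 0.12) and not called, but was called without double mutant replicate 2 (-0.37, adjusted p = 0.0193); IAA19 was at -0.09 (SE 0.27) and not called. Of 11 seed maturation genes 6 rose and 2 fell, also adjusted over the list alone, among them the storage protein genes CRU3 (3.82, SE 0.96), CRU1 (3.3, SE 0.87), SESA2 (2.82, SE 0.50) and SESA1 (2.48, SE 0.38). These varied within groups: CRU3 had 23.9, 87.1 and 58.0 TPM in the double mutant and 1.02, 1.40 and 74.7 TPM in h2a.z, and the list was not called against Col (adjusted p = 0.1771).

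The largest rises by the rule were AT4G24420 (5.01, SE 0.13), AT3G25719 (4.42, SE 0.25), AT5G66970 (14.2 ± 3.7 TPM, listed at 0 in Col), CRU3 and SESA5 (3.63, SE 1.12), of which SESA5 lost its call without Col replicate 2 (3.03, adjusted p = 0.0622). The largest falls were ESM1, a modifier of glucosinolate breakdown (-6.81, SE 0.11), JAL33 (-6.40, SE 0.11), CNGC12 (-5.75, SE 0.10), AT3G23510 (-5.0, SE 0.14) and GSTU8, a glutathione transferase (-4.99, SE 0.15). In total 9611 genes were called, 3826 higher and 5785 lower, and 1202 at least 2-fold, 376 higher and 826 lower. The share of higher calls was 39.8% as deposited and 50.6% (5042 higher, 4917 lower) with rescaled TPM. Plastid-encoded transcripts summed to 1864, 4198 and 2268 TPM in the 3 double mutant libraries and to between 1455 and 2055 TPM in the 9 others.

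**Figure D3:**
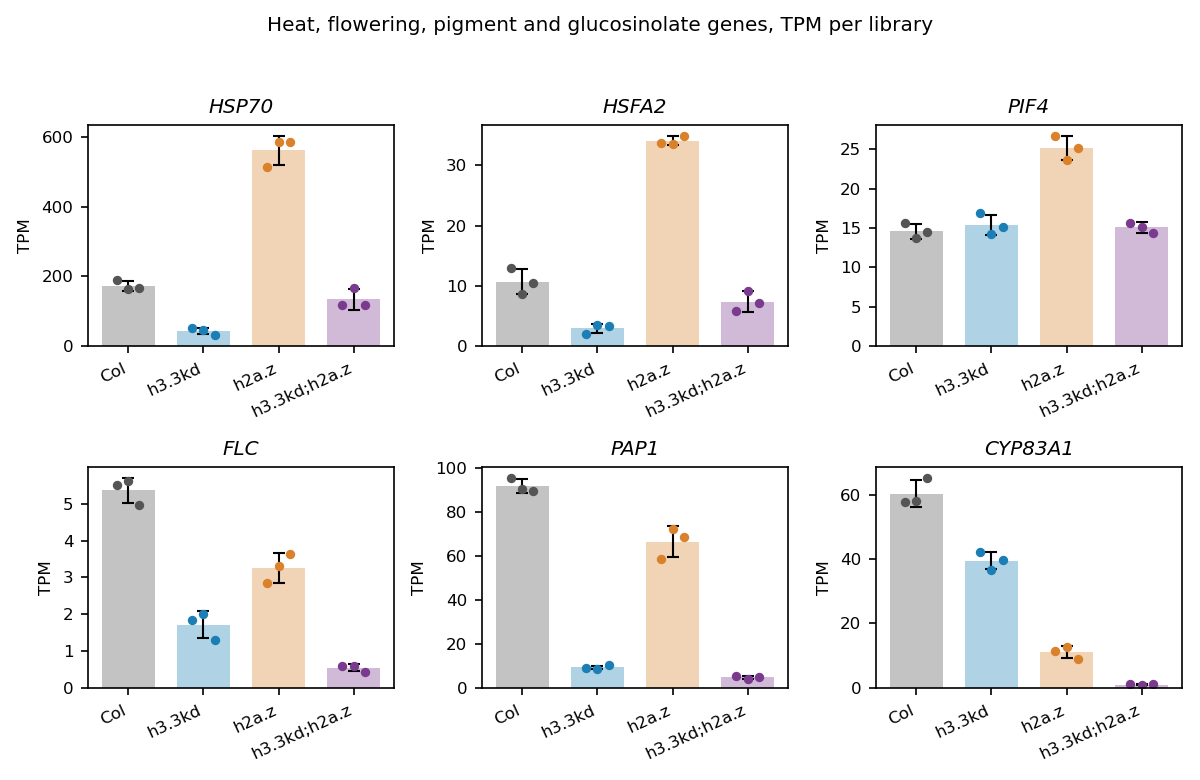
TPM (vertical axes, linear) of HSP70, HSFA2, PIF4, FLC, PAP1 and CYP83A1 in the 4 genotypes; points are single libraries, bars are means of 3 libraries and error bars are SD. HSP70 averages 173 TPM in Col, 42.8 in h3.3kd, 563 in h2a.z and 134 in the double mutant, and CYP83A1 is lowest in the double mutant (1.06 TPM).

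Against h2a.z, the double mutant differs by label in the H3.3 knockdown. The labels do not say whether both lines carry the same h2a.z alleles, and HTA9 stood at 60.5 TPM against 32.8 in h2a.z, so other differences between the lines are not separated from the knockdown. HSP70 fell by 2.09 (SE 0.15) and HSFA2 by 2.09 (SE 0.17), to 0.236 and 0.234 of the h2a.z level. PIF4 fell by 0.71 (SE 0.08), PIL1 by 0.92 (SE 0.15), EXPA8, an expansin gene, by 0.81 (SE 0.14) and XTR7 by 0.71 (SE 0.15).

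Of 18 heat shock genes 8 fell and none rose against h2a.z, also adjusted over the list alone; with rescaled TPM 8 fell and 2 rose, and the list was not called (adjusted p = 0.08598). Of 16 thermomorphogenesis genes 7 fell and 1 rose, also adjusted over the list alone, and the list was not called (adjusted p = 0.4894). Of 10 jasmonate genes 8 fell and none rose, also adjusted over the list alone, with VSP2 at -1.56 (SE 0.20), VSP1 at -1.34 (SE 0.16) and JAZ5 at -1.17 (SE 0.16). The list had an adjusted p of 0.007144 (adjusted p = 0.7254 with an estimated correlation), and of 0.0552 at a mean TPM of at least 5. Of 18 genes of abscisic acid, cold and drought 15 fell and none rose, or 16 adjusted over the list alone, with KIN1 at -2.47 (SE 0.11), COR6.6 at -1.48 (SE 0.11), RD22 at -1.39 (SE 0.07) and RD29B at -1.37 (SE 0.15); the adjusted p was 0.0001119 (adjusted p = 0.7254 with an estimated correlation). Of 20 photosynthesis genes 12 rose and none fell, also adjusted over the list alone, with LHCB1.2 at 1.35 (SE 0.08) and RBCS2B at 1.0 (SE 0.09); the adjusted p was 2.228e-06 (adjusted p = 0.7254 with an estimated correlation). HTR4 fell by 3.28 (SE 0.08) and HTR8 by 4.01 (SE 0.12), HTR5 was at -0.32 (SE 0.06) with a call lost under rescaled TPM (adjusted p = 0.0983), HTA11 fell by 0.52 (SE 0.12), and HTA8 was at -0.05 (SE 0.13) and not called. In total 9140 genes were called, 2673 higher and 6467 lower, and 1144 at least 2-fold, 248 higher and 896 lower. The median log2 fold change was -0.1207, and the share of higher calls was 29.2% as deposited and 52.7% (4923 higher, 4415 lower) with rescaled TPM.

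Against h3.3kd, the double mutant differs by label in the loss of H2A.Z, and other differences between the lines are not separated from it here either. All 18 glucosinolate genes fell, over all genes, adjusted over the list alone and with rescaled TPM, with CYP83A1 at -4.30 (SE 0.11), MAM1 at -3.39 (SE 0.12), CYP79F1 at -2.97 (SE 0.13) and CYP79F2 at -2.69 (SE 0.15). The list had an adjusted p of 2.867e-18 (adjusted p = 0.7254 with an estimated correlation).

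Of 18 heat shock genes 11 rose and none fell against h3.3kd, also adjusted over the list alone, with HSP18.2 at 1.69 (SE 0.15), HSP70 at 1.62 (SE 0.15), HSP90.1 at 1.43 (SE 0.10) and HSP17.8 at 1.34 (SE 0.19); the adjusted p was 0.001222 (adjusted p = 0.7254 with an estimated correlation). Of 20 photosynthesis genes 13 fell and none rose, or 14 adjusted over the list alone (adjusted p = 1.263e-06; adjusted p = 0.7254 with an estimated correlation). Of 19 cell cycle genes 7 fell and 1 rose, also adjusted over the list alone, among them the mitotic cyclin genes CYCA1;1 (-0.86, SE 0.20) and CYCB1;4 (-0.67, SE 0.17). That list had an adjusted p of 0.005961 (adjusted p = 0.7467 with an estimated correlation) and of 0.0682 without double mutant replicate 2. Of the targeted genes HTA8 fell by 3.19 (SE 0.13), HTA11 by 3.13 (SE 0.12) and HTA9 by 1.05 (SE 0.09), while HTR4 was at -0.04 (SE 0.08) and HTR5 at -0.16 (SE 0.06), neither called; HTR5 was called without double mutant replicate 2 (-0.22, adjusted p = 0.0144). HTR8 was at -0.33 (SE 0.12, adjusted p = 0.0483), a call lost when any single library other than h2a.z replicate 1 or double mutant replicate 2 was left out (adjusted p from 0.0541 to 0.196). In total 6536 genes were called, 3932 higher and 2604 lower, and 553 at least 2-fold, 264 higher and 289 lower. The share of higher calls was 60.2% as deposited and 50.3% (3501 higher, 3459 lower) with rescaled TPM.

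The interaction showed that for many genes the double mutant was not the sum of both single mutants. PIF4 had an interaction of -0.78 (SE 0.12, adjusted p = 0.000401), with a rise in h2a.z and a level near Col in the double mutant. Of 18 glucosinolate genes 15 had a negative interaction and none a positive one, or 18 adjusted over the list alone, led by CYP83A1 (-1.95, SE 0.16), MYB29 (-1.49, SE 0.20) and MYB51 (-1.28, SE 0.18). The list had an adjusted p of 3.081e-11 (adjusted p = 0.7254 with an estimated correlation). The most positive genes were AT4G16880, QQS, a gene of starch metabolism, and AT4G19500, each listed at 0 in all h2a.z libraries. They averaged 65.5, 5.4 and 22.6 TPM in Col and 37.6, 14.4 and 18.4 TPM in the double mutant. All belong to the genes more than 8-fold below Col in h2a.z described above. Whether both lines carry the same h2a.z alleles is not given, so other differences between the lines are not separated from the interactions given here. The most negative were MES18 (-3.44, SE 0.23), AT4G16857, a resistance gene (-3.32, SE 0.27) and AT3G16670 (-3.16, SE 0.42); MES18 had 66.2 TPM in h2a.z and 1.56 in the double mutant.

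Of 11 genes of the H2A.Z and H3.3 machinery 4 had a positive interaction and none a negative one, or 5 adjusted over the list alone. SWC6 (0.76, SE 0.16), a subunit gene of the H2A.Z-depositing complex, and INO80 (0.72, SE 0.12) led them. The list had an adjusted p of 0.006416 (adjusted p = 0.7254 with an estimated correlation). In h2a.z 6 of the 11 were called lower than in Col and none higher, and in the double mutant 1 was called higher than in Col and none lower. Of 19 cell cycle genes 3 had a negative interaction, or 6 adjusted over the list alone and 5 with rescaled TPM, among them MCM5, a replication helicase gene (-0.59, SE 0.16), whose call was lost without h3.3kd replicate 3 (adjusted p = 0.0637) or double mutant replicate 2 (adjusted p = 0.0526). That list had an adjusted p of 0.004559 (adjusted p = 0.7467 with an estimated correlation). Of 16 thermomorphogenesis genes 4 had a negative interaction, and adjusted over the list alone 4 a negative and 1 a positive one; XTR7 was at -0.91 (SE 0.21), and the list was not called (adjusted p = 0.6079). Of 18 genes of abscisic acid, cold and drought 6 had a negative interaction, also adjusted over the list alone, led by RD29B (-1.52, SE 0.21) and KIN1 (-1.02, SE 0.16). That list had an adjusted p of 0.02222 (adjusted p = 0.7443 with an estimated correlation), and of 0.156 without Col replicate 1 and 0.0673 without h2a.z replicate 3. Of 5 H3.1 genes 2 had a negative interaction, or 5 adjusted over the list alone (adjusted p = 0.02854; adjusted p = 0.7254 with an estimated correlation), a list call lost with a pseudocount of 0.1 (adjusted p = 0.146). HTR4 was at 0.10 (SE 0.11), HTR5 at -0.05 (SE 0.09), HTR8 at -0.24 (SE 0.17) and HTA8 at 0.06 (SE 0.18), none called. HTA11 was at -0.40 (SE 0.16) and not called, but was called without h3.3kd replicate 1 (-0.52, adjusted p = 0.0438) and with a pseudocount of 0.1 (-0.60, adjusted p = 0.045). In total 3298 genes had an interaction, 1394 positive and 1904 negative, and 546 of at least 2-fold; with rescaled TPM 1934 were positive and 1900 negative.

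Of the 8900 genes called in h2a.z, 71.93% had a smaller or opposite change in the double mutant against Col, where simulations with additive effects gave 59.7% on average and at most 60.6%. Among genes raised in h2a.z the share was 79.6% (simulated 69.7%) and among those lowered 59.8% (simulated 44.1%). With rescaled TPM they were 66.9% and 72.5%, so which share was larger depended on the scaling. No simulation was run with rescaled TPM, so these shares have no simulated value to compare with. The simulations take the h2a.z effect as equal in both backgrounds. HTA9 was at 60.5 TPM in the double mutant and 32.8 in h2a.z, so other differences between the lines are not separated from the knockdown. From separate libraries, a difference of h2a.z from Col and of the double mutant from h3.3kd was called for 4348 genes, 4039 of them in the same direction, with 3086 expected of independent lists. The fold changes in both backgrounds correlated at 0.60 across genes, where simulated additive effects gave 0.921. A difference of h3.3kd from Col and of the double mutant from h2a.z was called for 4493 genes, 4169 in the same direction, with 3279 expected and a correlation of 0.57. Both comparisons of a pair use the same variance estimate per gene, so genes of low spread tend to be called in both. The expected numbers of independent lists are therefore not a chance level for these calls.

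**Figure D4:**
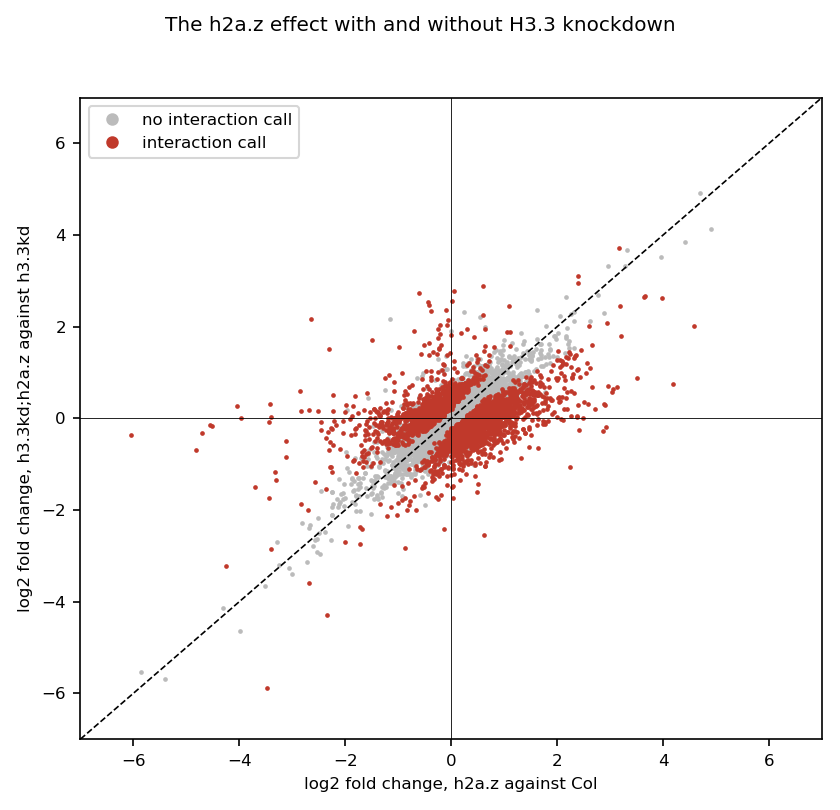
Log2 fold change of h2a.z against Col (horizontal axis) and of the double mutant against h3.3kd (vertical axis) for 18851 genes, each a point; red points are the 3298 genes with an interaction and the dashed line marks equal changes. The fold changes correlate at 0.60 across genes.

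The single mutants, both set against the same Col libraries, shared 762 higher and 1215 lower genes and moved 1612 in opposite directions. Independent lists would share 497 and 923, and no expected number was computed for the opposite genes. Simulated unchanged groups shared 0.02 and 0. Such groups have almost no calls to share, so these numbers say nothing about the observed overlap. With rescaled TPM 1187 were higher in both, 1056 lower in both and 1400 opposite. The balance of higher and lower thus depended on the scaling. The fold changes correlated at 0.121 across genes, below the 0.50 that shared controls alone gave in simulation, and their covariance was 0.0239 against a simulated 0.00769, a difference of 0.0162. No split of 3 Col libraries leaves at least 2 in each part and the controls were not split, so part of the overlap may come from them. At least 2-fold, 21 genes were higher in both, 43 lower in both and 47 opposite.

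**Figure D5:**
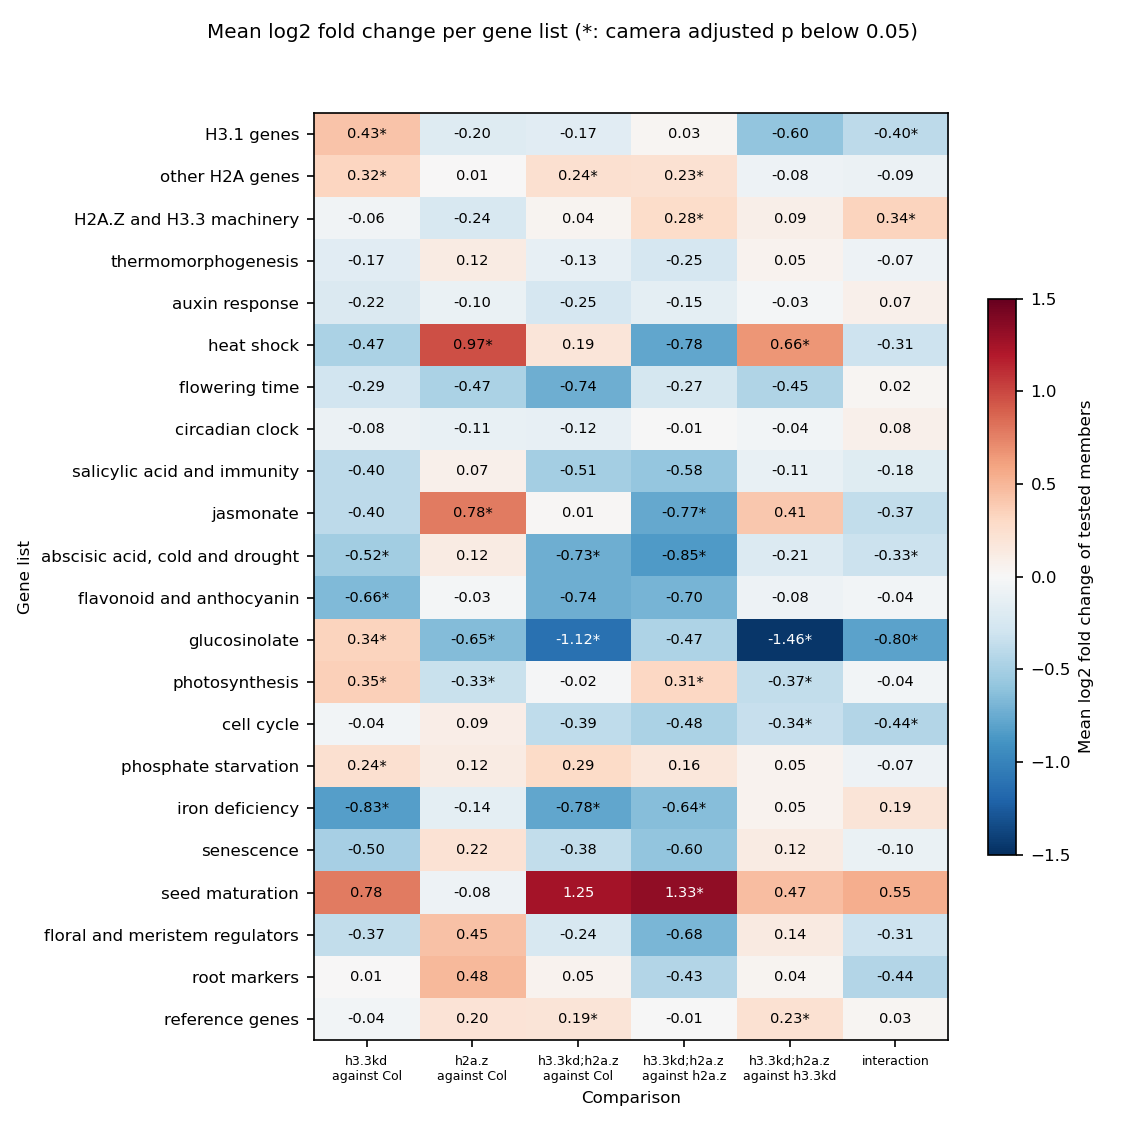
Mean log2 fold change of the tested members of 22 gene lists (vertical axis) in 6 comparisons (horizontal axis), with the color scale in log2 units and a star where the camera test with its preset correlation was called. Heat shock averages 0.97 in h2a.z and -0.47 in h3.3kd, and glucosinolate -1.46 in the double mutant against h3.3kd.

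The remaining lists gave fewer calls. Seed maturation genes were higher in the double mutant than in h2a.z, 6 up and 1 down, or 7 and 1 adjusted over the list alone (adjusted p = 0.007989; adjusted p = 0.7254 with an estimated correlation), a list call lost with rescaled TPM (adjusted p = 0.119) and without double mutant replicate 3 (adjusted p = 0.0659). Of 11 genes of the H2A.Z and H3.3 machinery 6 were lower in h2a.z than in Col and none higher, also adjusted over the list alone. Their mean log2 fold change was -0.24 (camera adjusted p = 0.05073). In the double mutant against Col the mean was 0.04, with 1 called higher, or none adjusted over the list alone. Of the same 11 genes 6 were higher in the double mutant than in h2a.z and none lower, also adjusted over the list alone. The adjusted p was 0.00389, and 0.7254 with an estimated correlation. Of 13 iron deficiency genes 8 were lower and 1 higher in that comparison, also adjusted over the list alone (adjusted p = 0.04364; adjusted p = 0.7254 with an estimated correlation), a list call lost without h2a.z replicate 2 (adjusted p = 0.0525) or double mutant replicate 1 (adjusted p = 0.125). Of 9 other H2A genes 5 were higher and 1 lower there, also adjusted over the list alone. That list had an adjusted p of 0.02222 (0.7254 with an estimated correlation), of 0.0511 with rescaled TPM and of 0.0774 without h2a.z replicate 3. Against Col 5 were higher and 2 lower in the double mutant, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.049, and 0.7254 with an estimated correlation). This call was lost with rescaled TPM (adjusted p = 0.0789) and at a mean TPM of at least 5 (0.0548). It was also lost without Col replicate 1 or 2, h3.3kd replicate 1, h2a.z replicate 2 or double mutant replicate 2 or 3 (0.0513 to 0.065).

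Reference genes, 12 commonly used for normalization, were higher in the double mutant than in Col, 6 up and 1 down or 7 and 1 adjusted over the list alone (adjusted p = 0.01502), and than in h3.3kd, 8 up and none down, also adjusted over the list alone (adjusted p = 0.002531), or 5 up and none down with rescaled TPM. Each had an adjusted p of 0.7254 with an estimated correlation, and their mean log2 fold changes were 0.19 and 0.23. In h2a.z against Col 6 were up and none down, or 6 and 1 adjusted over the list alone. Their mean there was 0.20, and the list was not called (camera adjusted p = 0.1019). The double mutant against h2a.z had 3 up and 3 down, so the shift was not particular to the double mutant. The lists of auxin response, circadian clock, salicylic acid and immunity, senescence, floral and meristem regulators and root markers were not called in any comparison. In h3.3kd 3 of 13 auxin response genes rose and 6 fell, 1 of 14 circadian clock genes rose and 4 fell, 6 of 9 genes of salicylic acid and immunity fell, and 4 of 9 senescence genes fell. In h2a.z 6 of 11 root marker genes rose and 1 fell (adjusted p = 0.1105), and 2 of 3 floral and meristem regulators rose (adjusted p = 0.2454). The 6 counts were the same adjusted over the list alone. With rescaled TPM 3 circadian clock genes rose and 1 fell in h3.3kd, 1 gene of salicylic acid and immunity rose and 3 fell, and 1 senescence gene rose and 3 fell. The balance for circadian clock genes thus depended on the scaling. No list was called in any of the 132 tests with an estimated correlation, where the smallest adjusted p was 0.7254.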

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

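The interaction was planned before the data were examined, and the genes below are those named by the fixed rule that had one; only the comparison of residual SD between regroupings was chosen after the result was seen. All results here stand out because the difference between genotypes with and without the H3.3 knockdown itself differed between the Col and h2a.z backgrounds, by the limma test of the interaction. Whether the h2a.z alleles are the same in both lines is not given, so other differences between the lines are not separated from it. In total 3298 genes differed in this way. Of 100 regroupings of the 12 libraries, the real one included, 2 gave as many genes, and the highest other regrouping gave 5135. The other 99 regroupings mix the genotypes and had a median residual SD of 1.53 to 2.05 times that of the real one, which by itself lowers the number of calls, so these regroupings do not show whether chance can be excluded.

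The mean log2 interaction of whole lists was -0.80 for glucosinolate genes, -0.44 for cell cycle genes, -0.40 for H3.1 genes, -0.33 for genes of abscisic acid, cold and drought and 0.34 for the H2A.Z and H3.3 machinery. With an estimated correlation none of these lists was called (adjusted p = 0.7254 to 0.7467).

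Of 18 glucosinolate genes 15 had a negative interaction and none a positive one, with -2.4 for ESM1, a modifier of glucosinolate breakdown outside the list, -1.95 for CYP83A1, -1.49 for MYB29, -1.28 for MYB51, -1.23 for SOT17, -1.0 for MAM3 and -0.68 for CYP79F2. Of 18 heat shock genes 3 had a negative and 1 a positive interaction, with -1.79 for HSP17.6C and -1.55 for HSP17.6II. HSP70 was not among the named genes with an interaction. Of 10 jasmonate genes 2 had a negative and 1 a positive one, -1.72 for LOX2, -0.92 for VSP2 and 0.54 for CORI3. Neither list was called (camera adjusted p = 0.6549 for heat shock and 0.1671 for jasmonate), and of all genes tested 17.5% had an interaction. RD29B had -1.52, KIN1 -1.02, COR6.6 -0.75 and RD22 -0.39, all of the abscisic acid, cold and drought list, and PAP2 had -1.16.

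Of 16 thermomorphogenesis genes 4 had a negative interaction and 12 were not called, and the list was not called (adjusted p = 0.6079): XTR7 had -0.91, PIF4 -0.78, PIL1 -0.7 and TAA1 -0.31. PIL1 lost its call with a pseudocount of 0.1 and without replicate 2 or 3 of any genotype (adjusted p from 0.054 to 0.0793), and TAA1 without Col replicate 2 or h3.3kd replicate 1 or 2 (adjusted p from 0.0502 to 0.0613).

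Of 19 cell cycle genes 3 had a negative interaction and 16 were not called: -0.71 for MCM7, -0.59 for MCM5 and -0.45 for PCNA2. MCM5 lost its call without h3.3kd replicate 3 or double mutant replicate 2 (adjusted p = 0.0637 and 0.0526). MCM7 lost it without replicate 2 or 3 of Col, h3.3kd or the double mutant or replicate 1 or 2 of h2a.z (adjusted p from 0.0536 to 0.071). PCNA2 kept it only without h2a.z replicate 3 or double mutant replicate 1, and otherwise had an adjusted p from 0.0636 to 0.102.

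Of the histone genes named, the values were -0.44 for HTR2, -0.42 for HTA7, -0.4 for HTR1, 0.41 for HTA1, 0.51 for HIS1-3 and 1.22 for HTA9, an H2A.Z gene. Of the machinery genes SWC6 had 0.76, INO80 0.72, CABIN1 0.53 and ATRX 0.42. CABIN1 lost its call without Col replicate 1 or 2, any h3.3kd replicate, h2a.z replicate 3 or double mutant replicate 2 or 3 (adjusted p from 0.0556 to 0.0945). ATRX lost it without Col replicate 1 or 2, h3.3kd replicate 2 or 3 or h2a.z replicate 2 (adjusted p from 0.052 to 0.06).

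Of 13 iron deficiency genes 5 had a positive and 2 a negative interaction, and the list was not called (adjusted p = 0.08985): IMA2 had 1.14, PYE 0.92, IMA1 0.9 and NAS4 0.32. Of 20 photosynthesis genes 2 had a negative and 1 a positive interaction, among them LHCB4.2 with -0.39 and LHCB1.2 with 0.38, and none was called with rescaled TPM. The photosynthesis list was not called either (camera adjusted p = 0.7075).

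Further calls named here were lost in some settings. With rescaled TPM these were HTA7 (adjusted p = 0.0519), RD22 (0.0562), LHCB4.2 (0.0915) and LHCB1.2 (0.113; 0.0574 with the replicate number as a block), and with a pseudocount of 0.1 they were VSP2 (0.52), CYP79F2 (0.526), IMA1 (0.0574), AT3G44970 (0.0704) and AT3G23510 (0.289). When 1 library was left out, CYP79F2 kept its call only without h2a.z replicate 3 or double mutant replicate 1 or 3 and otherwise had an adjusted p from 0.0577 to 0.0924, and IMA1 only without Col replicate 2, h3.3kd replicate 3 or double mutant replicate 1 (otherwise from 0.0637 to 0.1). VSP2 lost it without Col replicate 1 or 2, h3.3kd replicate 1 or 2, h2a.z replicate 1 or 3 or double mutant replicate 3 (adjusted p from 0.0578 to 0.0894). HIS1-3 lost it without Col replicate 1 or 2, h3.3kd replicate 2 or 3, h2a.z replicate 1 or 2 or double mutant replicate 2 (adjusted p from 0.0685 to 0.115). LHCB1.2 lost it without Col replicate 2 or 3, h3.3kd replicate 1 or 2, h2a.z replicate 2 or 3 or double mutant replicate 3 (adjusted p from 0.0518 to 0.0821). HTA7 lost it without Col replicate 1 or 3, h3.3kd replicate 2 or 3 or double mutant replicate 3 (adjusted p from 0.0517 to 0.07), and HTA1 without Col replicate 1 or 2, h3.3kd replicate 1 or double mutant replicate 2 (from 0.0536 to 0.0663). AT3G44970 lost it without Col replicate 1, h3.3kd replicate 3, h2a.z replicate 2 or double mutant replicate 2 (adjusted p from 0.0505 to 0.0652), NAS4 without Col replicate 3, h3.3kd replicate 2 or h2a.z replicate 1 (from 0.0506 to 0.0752), and HTR2 without Col replicate 2 or 3 (0.0528 and 0.0501).

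Of the genes with the largest changes, AT4G16880 had 5.69, QQS 4.81, AT4G19500 4.42, AT1G13609 4.37, AT3G28270 4.13, AT3G23510 1.04 and AT3G44970 0.57. Negative values were -3.44 for MES18, -3.32 for AT4G16857, -3.16 for AT3G16670, -2.57 for AT3G28320, -1.95 for AT5G03090, -1.9 for AT1G14250 and -1.77 for AT2G05915. AT4G16880, QQS and AT4G19500 were listed at 0 in h2a.z and AT3G28320 in Col and h3.3kd, so that their values depend on the pseudocount and bound nothing.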

How the results depend on the processing

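The alternatives were fixed before the data were examined except for 3 chosen after the results were seen: leaving out genes near nearly silent genes, leaving out organelle-encoded genes, and TPM recomputed without the 100 most abundant genes. No called result reversed under any alternative run. Of 245 gene results, the interactions of all genes named among them, 934 runs of planned settings gave 917 with the same call, 16 weaker and 1 stronger, and 2940 runs without 1 library gave 2807, 129 and 4. Of 34 list calls, 204 planned runs gave 158 with the same call and 46 weaker, and 408 runs without 1 library gave 394 and 14.

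Counts of called genes stayed within 1.5 times except with a 2-fold minimum, which by its construction keeps fewer genes: 503 for h3.3kd, 965 for h2a.z and 1202 for the double mutant against Col, 1144 against h2a.z, 553 against h3.3kd, 546 for the interaction and 64 for the overlap of both single mutants (1977 without the minimum). The share of h2a.z changes that were smaller or opposite in the double mutant was 70.4% at a mean TPM of at least 5, 69.75% with rescaled TPM and 77.62% with the 2-fold minimum; the cause was not tested. Camera called 0 lists with an estimated correlation and fry called 70, keeping 29 of the 34.

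Without 1 library in turn the counts ranged from 5117 to 7300 for h3.3kd, 7648 to 9382 for h2a.z and 8322 to 9971 for the double mutant against Col. They ranged from 8019 to 9547 against h2a.z, 5043 to 6996 against h3.3kd, 2388 to 4152 for the interaction, 1450 to 2188 for the overlap, 70.73% to 73.14% for the share of shifted genes and 32 to 40 for list calls.

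The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.17 to 0.077 across genes in 18 pairs, and 1 of 12 libraries correlated best with its own number. With the replicate number as a block 6405, 8638, 9343, 8888 and 6243 genes were called in the pairwise comparisons, in the order above, 2938 had an interaction and 36 lists were called.

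Without genes within 10 positions of a nearly silent gene, 8064 genes were called in h2a.z, 8289 in the double mutant against h2a.z and 2890 for the interaction. Without organelle-encoded genes 9583 were called in the double mutant against Col. In h2a.z replicate 1 the low depth makes values of low genes coarse, and fewer genes were above 0 there (21252) than in the other libraries (21804 to 22333).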

Other observations

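Among the tests of this part, those of annotated gene groups, of the clustering of nearly silent genes, of loss of H2A.Z alone and of RNA without a poly(A) tail were chosen after the results they concern were seen. Of 30 genes annotated as histones 20 were higher and 4 lower in h3.3kd than in Col (camera adjusted p = 3.191e-10; adjusted p = 0.9936 with an estimated correlation). This group includes the targeted genes HTR4 and HTR8, both among the lower ones. It also includes HTR1, HTR2, HTR3 and HTA1 of the lists described above, so it is not a separate observation from those lists. In h2a.z 9 of 10 late embryogenesis abundant genes, which encode protective proteins of seeds and dry tissue, were lower and none higher (adjusted p = 0.0001598; adjusted p = 0.9936 with an estimated correlation), and 9 were higher in the double mutant than in h2a.z (adjusted p = 0.002094; adjusted p = 0.9936 with an estimated correlation). Of 49 peroxidase genes 29 were higher and 4 lower in h2a.z (adjusted p = 0.02362; adjusted p = 0.9936 with an estimated correlation), and the interaction was negative for 22 and positive for 1 (adjusted p = 7.024e-08; adjusted p = 0.9936 with an estimated correlation). Of 56 genes with a C1 domain 37 were higher and 2 lower in h2a.z (adjusted p = 0.002872; adjusted p = 0.9936 with an estimated correlation).

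In the double mutant 152 of 310 nuclear genes of ribosomal proteins were higher than in Col and 42 lower (adjusted p = 4.94e-07; adjusted p = 0.9936 with an estimated correlation). In h3.3kd 20 were higher and 35 lower as deposited, but 74 higher and 10 lower with rescaled TPM, so the direction there depended on the scaling. Of 102 resistance genes of the NBS-LRR class 48 were lower and 5 higher in the double mutant than in Col (adjusted p = 0.02876; adjusted p = 0.9936 with an estimated correlation), or 44 and 10 with rescaled TPM. None of the 177 groups was called with an estimated correlation.

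The 46 genes nearly silent in h2a.z lay close together on the chromosomes: 12 adjacent pairs were within 50 gene positions, against 5.18 on average in 10000 random draws (permutation p = 0.0014). The same test found 0 such pairs among 25 genes in h3.3kd (permutation p = 1) and 14 among 65 in the double mutant (mean of draws 10.1, permutation p = 0.107). Targeted genes were not left out of these tests. HTA8 and HTA11 are among the 46, HTR4 and HTR8 are among the 25, and all of these are among the 65. Of the 46 genes, 93.5% were also nearly silent without h2a.z replicate 1, so most of the low means do not rest on that shallow library. A mean of 3 libraries more than 8-fold below Col left little room for another outcome. The clustering was not tested again without that library, so its low depth is not decided on as a source of the clustering. In the double mutant 54.3% of the 46 genes were under 25% of Col, but HTA9 was higher there than in h2a.z, so this does not decide on loss of H2A.Z alone, which stays open. Chromosome segments from another strain stay open as a candidate explanation: neighbours within 10 positions changed at least 2-fold 1.87 times as often as other genes, outside the random range of 0.688 to 1.34, with 29 higher and 39 lower. No genotype calls or sequence were used here, and an effect of H2A.Z on neighbouring genes remains open and untested.

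Of 73 plastid-encoded genes 58 were called higher in the double mutant than in h3.3kd and none lower, while in h3.3kd 10 were lower than in Col and none higher, 30 and 1 when double mutant replicate 2 was left out of the fit, and 5 and none with rescaled TPM. Their sum was highest in double mutant replicate 2. That library as the sole source of the difference from h3.3kd is argued against, as 45 were higher and 2 lower without it. Against Col 36 were higher and 2 lower (mean log2 fold change 0.799), but 25 and 7 without it (0.414), and double mutant replicate 1 had a sum of 1864.2 TPM against 1899.7 to 2055 in Col, so a rise above Col rests in large part on that library. Carry-over of RNA without a poly(A) tail stays open as a candidate explanation: mitochondria-encoded genes, which share that property, had a mean log2 fold change of 0.491 (SE over 17 genes 0.0611) against h3.3kd, with 6 called, and without double mutant replicate 2 of 0.26 (SE 0.0646), with 2 called. A change in plastid transcription in the double mutant was not tested.

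In h3.3kd 25.4% of the calls were higher than in Col. Gene length bias is argued against as the whole cause, as the share was at most 30% in any of 5 groups of genes by exonic length. It was 15.3% in the longest genes and 25.7% to 30% in the other groups, so a part played by length stays open. A few abundant genes taking more of the TPM total may account for much of the imbalance: the 100 most abundant genes held 35.4% to 36.6% of the total in h3.3kd and 30.3% to 32.0% in Col, and without them 45.8% of the calls were higher. A fall of total transcript amount per cell would not appear in TPM and was not tested.

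For each pairwise comparison the 6 libraries allow 10 splits, too few for a share under 0.05. The real split was the 1 with as many calls in each. The highest other split gave 1 gene for the double mutant against h2a.z and 0 for the other comparisons. Each other split mixes both genotypes, which by itself lowers the number of calls, so these splits do not show whether chance can be excluded.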
